A study of Arabidopsis thaliana with 18 samples.

How the data were processed

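Shoots of 14-day-old seedlings grown on Murashige and Skoog plates with sucrose under short days (8 h light at 22 °C and 16 h dark at 18 °C) were used throughout, per the labels' protocols. mRNA was enriched with oligo(dT) beads and copied with random hexamers, and chromatin was immunoprecipitated with an antibody against H3K27me3, per the labels' protocols. The labels place 18 libraries in 9 groups: mRNA of Col clf, C24 clf and clf F1 with 3 libraries each, H3K27me3 of wild-type Col, C24 and F1 with 2 each, and H3K27me3 of clf Col, clf C24 and clf F1 with 1 each. Replicate numbers come from the labels. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

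The mRNA values are deposited RPKM, 1 file per library with 1 value per gene. Their unit was read from the values: library sums ran from 728340 to 767000, and values of short genes moved in steps that shrink with gene length. TopHat, Bowtie and the TAIR10 build are named in the submitters' processing notes, with no version, role or order. The counting program, the annotation release, the treatment of reads with several positions and of strand, and any input or control for the peaks are not given in the sources used here. Without strand, reads of a gene and of an overlapping or antisense partner cannot be told apart. The peak lists give the start and end of each peak, a tag number, a score and a fold enrichment. The tag numbers are counts of tags per peak deposited by the authors and not normalized. The score and the fold enrichment of each peak are the authors' own values from their peak caller, and every deposited score was at least 50. The peak caller is not given in the sources used here. Peaks were deposited per library, not pooled, and positions were read as 1-based with both ends included. Scores and folds were used to describe, rank or filter peaks within a list.

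The mRNA files hold no counts, so the test for normalized values fixed beforehand was used in place of a count test. Depth was estimated from the value of 1 read in genes of up to 400 bp. It came to 16.4, 20.7 and 22.05 M reads in Col clf replicates 1, 2 and 3, 24.03, 18.4 and 14.9 M reads in C24 clf and 19.6, 22.1 and 20.05 M reads in clf F1. At these depths 68.2% to 77.9% of values of up to 4 reads lay within 4% of a whole number of reads, against a median of 8.22% to 10.9% over the trial depths. Whole reads were not recovered for all genes, because gene lengths used by the authors are not given in the sources used here. An exact 0 is reported as listed at 0, since LHCB1.3, an abundant antenna gene, was listed at 0 in all libraries. Of 34133 lines per file, 1141 lines of 567 repeated gene IDs were left out, which left 32992 genes. No pair of the 9 mRNA libraries shared more than 0.971% identical values over tested genes (36 pairs), so none was treated as a duplicate.

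Genes with at least 1 RPKM in at least 3 libraries were kept (17819). log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with a trended prior, 1 coefficient for each of the 3 groups and a shared spread. log2 differences are on this scale, which understates changes of genes near 1 RPKM. Benjamini-Hochberg adjusted p below 0.05 was the threshold. The mid-parent was the arithmetic mean of the fitted levels of both parents, back on the 2^x scale, with a delta-method standard error and limma's moderated variance. A gene lay outside both parents where it passed in both F1 comparisons with the same sign. As these share the F1 libraries, unchanged groups were simulated in 20 draws, which gave 0 such genes. The simulated groups all had equal levels, so the draws do not give the number to be had where the parents differ. Tests were tried on simulated data with the 17819 genes' levels and spreads and 200 changed genes. For C24 against Col, 68% of 1.5-fold, 82% of 2-fold and 99% of 4-fold changes were recovered with 11 false calls among 17619 unchanged genes. For the mid-parent, 80%, 88% and 100% were recovered with 13 false calls, and the mean of logs gave 252. Noise was drawn independently for each gene and library, without anything that libraries of the same replicate number share. The false calls therefore do not give the number to be had in these data.

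Gene lists (14, among them root markers as a sign of other tissue) were fixed before the data were examined and matched by gene ID. They were tested with camera at a preset correlation of 0.01 and again with the correlation estimated for each list, adjusted over the 13 lists with at least 2 tested members. The root list has 1 tested member and no list test. camera compares F1 with the mean of the parents' logs. Genes named were taken by a rule fixed before the data were examined. CLF came first. For C24 against Col and for F1 against the mid-parent, it took the 10 highest and 10 lowest log2 differences among called genes. Their libraries had to lie apart (for the mid-parent, all F1 libraries on 1 side), with at least 10 RPKM in the higher group and a symbol other than the ID. It also took up to 4 members per list by p, 12 loci fixed by name for the mark, the 5 genes with the greatest covered length per marking set, and the 5 largest changes with and against a mark in 1 clf parent. ZAR1 in C24 against Col, DMR6, WAK1 and TGG2 as genes outside both parents, and the rRNA gene AT3G41979 were named after their values were seen, as were SWN, SEP3, KNAT3 and KNAT4 for the replicate block.

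Gene symbols and positions for assigning peaks came from a table of the TAIR10.1 assembly, and 32248 of the gene IDs matched it on chromosomes 1 to 5. The files use TAIR10. Shifting the peaks of wild-type C24 replicate 1 and of clf F1 by 2000 bp or more weakened the relation between coverage and low mRNA on each chromosome. The check was run on these lists alone. The table was therefore used to assign peaks, and printed positions are those of the deposited peaks. A gene was marked where peaks covered at least 200 bp of it, or all of a shorter gene. Shares carry exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Lists were compared with all other genes of chromosomes 1 to 5 by two-sided Fisher's exact tests adjusted over 14 lists. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and plots made with matplotlib 3.10.9.

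Replicate numbers were checked for pairing before the fits were compared. Deviations from group means correlated at 0.169 to 0.426 in all 9 pairs of mRNA libraries of the same number and at -0.275 to -0.002 in the 18 other pairs, so the numbers pair the libraries and a fit with the replicate number as a block was run. The pairing comes from this check, since the labels do not say what a number shares. The other alternatives fixed beforehand were quantile normalization, no filter, a filter of 5 RPKM, pseudocounts of 0.1 and 0.01, nuclear genes alone, the fit of the compared groups alone, a 2-fold minimum, the mean of logs, each library left out in turn, any overlap, at least 50% of the gene body, the 50% of peaks with the highest scores, equal numbers of peaks and merged regions. Added after the data were seen were fits without organelle and rRNA genes, fits without the 3 libraries richest in rRNA (Col clf replicate 2 and clf F1 replicates 2 and 3), and wild-type calls from replicate 1 or replicate 2 lists alone. The labels give no sequencing batch. Alleles were not told apart in the F1, and wild-type mRNA was not analysed here.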

Results

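Shoots of 14-day-old Arabidopsis thaliana seedlings were profiled in the accessions Col and C24 and in their F1 hybrid, to ask how trimethylation of histone H3 at lysine 27 (H3K27me3) differs between the accessions and what the hybrid keeps of it. H3K27me3 marks genes silenced by the Polycomb repressive complex, and CURLY LEAF (CLF) is a histone methyltransferase of that complex. H3K27me3 was mapped by ChIP-seq in wild-type Col, C24 and F1 with 2 libraries each, and in clf mutants of Col, C24 and their F1 with 1 library each. mRNA was sequenced in the clf mutants alone, with 3 libraries each of Col clf, C24 clf and clf F1. The Col mutant carries a T-DNA insertion, and the C24 mutant carries an induced point mutation in the SET domain of CLF. Step sizes of the RPKM values (reads scaled to gene length and library size) corresponded to 14.9 M reads in C24 clf replicate 3, the shallowest library, and to 24.03 M reads in C24 clf replicate 1, the deepest.

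CLF mRNA itself (AT2G23380) separated the 3 mutant groups. Col clf libraries held 1.21, 0.99 and 1.37 RPKM, C24 clf libraries 7.20, 7.14 and 8.35 RPKM, and clf F1 libraries 4.35, 3.93 and 4.08 RPKM. The insertion mutant thus had the lowest CLF level, at 1.19 ± 0.19 RPKM (SD, n = 3), against 7.56 ± 0.68 RPKM in the point mutant. The difference of 1.97 on the log2(RPKM + 1) scale (SE 0.098) had a limma adjusted p of 2.2e-08. The F1 mean of 4.12 ± 0.21 RPKM lay at the arithmetic mid-parent of 4.38 RPKM, with a difference of -0.07 and an adjusted p of 0.599. CLF levels in wild-type shoots were not analysed here.

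The comparison of C24 clf with Col clf asked which genes differ between the 2 mutants. Accession and clf allele differ together here, so no difference can be assigned to the accession or to the allele. Of the genes higher in C24 clf and named by size of change, the first was ESP (AT1G54040), the epithiospecifier protein that diverts glucosinolate breakdown towards nitriles, with 17.2 ± 2.31 RPKM in Col and 2567 ± 49.6 RPKM in C24. AOP2 (AT4G03060), a side-chain modifying dioxygenase of the same pathway that the reference annotates as a transcribed pseudogene, had 2.55 ± 0.57 RPKM in Col and 359 ± 65.4 RPKM in C24. The cruciferin storage protein genes followed, CRU3 (AT4G28520) at 0.617 against 72.0 RPKM and CRA1 (AT5G44120) at 1.12 against 42.1 RPKM, and M17 (AT2G41260) at 0.743 against 53.2 RPKM. The storage protein levels were uneven among the C24 libraries, with SDs of 43.1 and 25.1 RPKM for CRU3 and CRA1. HPL1 (AT4G15440), a hydroperoxide lyase, had 1.44 RPKM in Col and 64.0 RPKM in C24, the glyoxylate cycle enzyme ICL (AT3G21720) 0.423 and 20.1 RPKM, and PCC1 (AT3G22231) 9.10 ± 9.99 and 99.3 ± 8.94 RPKM. Of the SADHU retroelements, SADHU3-2 (AT3G42658) had 0.387 RPKM in Col and 18.1 RPKM in C24, and SADHU3-1 (AT3G44042) was listed at 0 in all Col libraries and had 16.9 ± 2.55 RPKM in C24.

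Genes far lower in C24 clf included ECS1 (AT1G31580), at 256 ± 16.1 RPKM in Col and 0.0967 ± 0.167 RPKM in C24, a log2 difference of -7.88 with an adjusted p of 2.6e-13. The arginase gene ARGAH2 (AT4G08870; 69.1 ± 20.4 RPKM in Col) and SADHU1-1 (AT2G10410; 66.8 ± 5.84 RPKM in Col) were listed at 0 in all C24 libraries. The resistance gene RLM3 (AT4G16990) had 103 RPKM in Col and 4.99 RPKM in C24, and HR4 (AT3G50480), a homolog of RPW8, 15.9 and 0.14 RPKM. ESM1 (AT3G14210), which counteracts nitrile formation during glucosinolate breakdown, had 228 ± 18.5 RPKM in Col and 24.4 ± 4.0 RPKM in C24. Near-identical copies can share reads, so the values of LpxC2 (AT1G24880; 69.3 and 0.0167 RPKM), LpxC3 (AT1G25054; 11.5 and 0.11 RPKM) and the 2 AT14A genes (10.7 and 0.257 RPKM for AT3G28300, 11.1 and 0.37 RPKM for AT3G28290) are uncertain. All 20 of the genes taken by size of change kept their calls in every setting run.

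Of 17819 genes tested with limma, 7935 (44.5%) differed at an adjusted p below 0.05, 5675 higher and 2260 lower in C24, with 770 and 493 of them at least 2-fold apart. Library ranges did not overlap between the groups for 9877 genes (55.4%), where chance gives 10%. The median log2 difference of all tested genes was 0.13, and quantile normalization took it to 0.01 and the calls to 3833 higher and 3623 lower. Of the 7935 genes, 6037 (76.1%) were called again with it. Reads were placed on TAIR10, which is the Col sequence, so C24 sequence differences could not be separated from lower C24 mRNA.

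**Figure D1:**
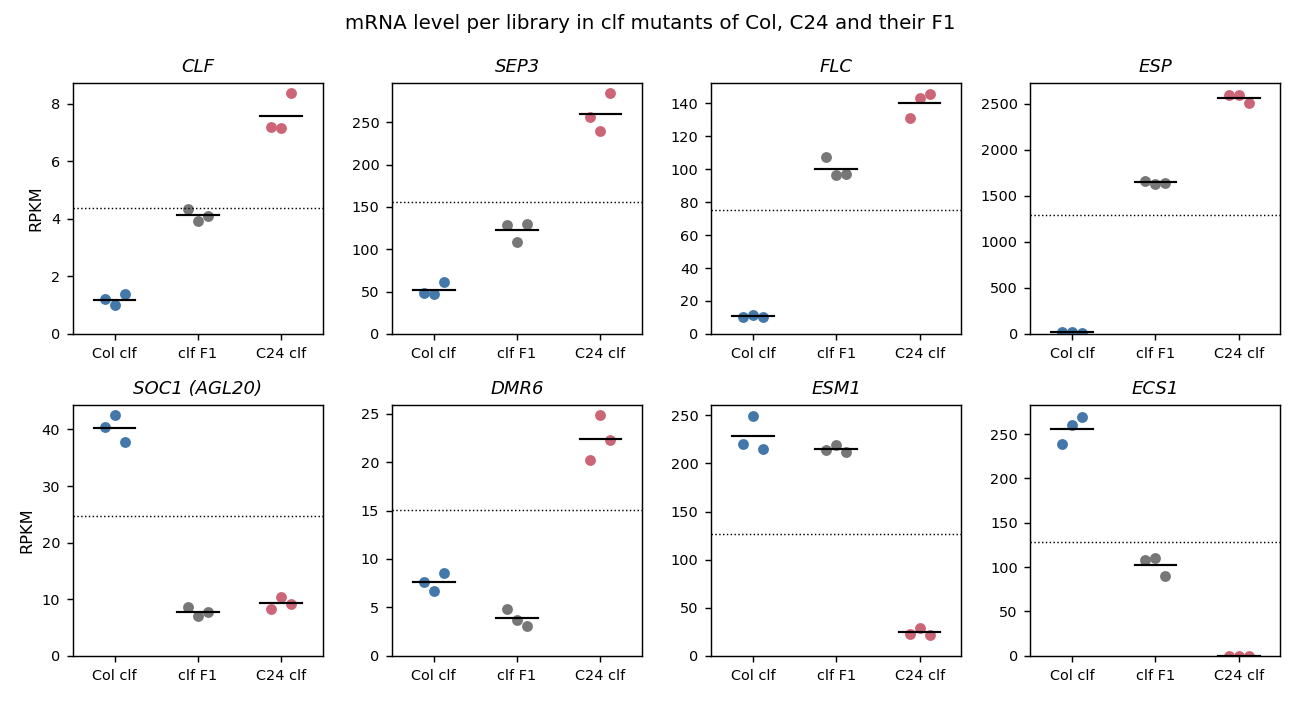
mRNA level in RPKM (vertical axes, linear from 0) of 8 genes in Col clf, clf F1 and C24 clf. Points are the 3 libraries of each group, solid lines group means and dotted lines the arithmetic mid-parent; SOC1 and DMR6 lie below the mid-parent in the F1, and FLC and ESM1 above it.

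Among the gene groups fixed before the data were examined, floral organ identity and related MADS-box genes were higher in C24 clf. Of 12 tested members 10 were higher and 0 lower, or 11 and 0 adjusted over the list alone, and their median log2 difference was 1.04 against 0.13 for all genes. SEP3 (AT1G24260), a floral homeotic gene, had 52.1 ± 8.08 RPKM in Col and 260 ± 22.7 RPKM in C24, PI (AT5G20240) 1.62 and 10.01 RPKM, AP3 (AT3G54340) 0.413 and 4.0 RPKM and STK (AT4G09960) 0.327 and 2.51 RPKM. The camera adjusted p was 1.6e-04, and the adjusted p = 0.233 with an estimated correlation. Of 9 meristem genes 5 were higher and 0 lower, both over all genes and adjusted over the list alone, including STM (AT1G62360) at 2.46 against 6.37 RPKM and KNAT1 (AT4G08150) at 2.18 against 5.32 RPKM, although the list did not pass (adjusted p 0.107). Among 21 Polycomb and demethylase genes 9 were higher and 1 lower, or 10 and 1 adjusted over the list alone, with SWN (AT4G02020), a paralog of CLF, at 14.0 and 26.8 RPKM and EMF1 (AT5G11530) at 6.30 and 13.2 RPKM. That list did not pass (adjusted p 0.129), and quantile normalization left 4 higher and 2 lower calls. Of 8 seed genes 6 were higher and 1 lower by both adjustments. AGL38 (AT1G65300), also named PHE2, had 0.26 and 12.1 RPKM, and DOG1 (AT5G45830), a regulator of seed dormancy, was the lower one at 4.24 and 1.51 RPKM. The seed list had a camera adjusted p of 0.129, or 0.433 with an estimated correlation. Its adjusted p was 0.0159 with a filter of 5 RPKM and 0.0491 without clf F1 replicate 2.

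Flowering time genes were divided, with 8 of 22 higher and 9 lower in C24 clf, or 9 and 9 adjusted over the list alone. FLC (AT5G10140), a repressor of flowering, had 10.6 ± 0.65 RPKM in Col and 140 ± 7.96 RPKM in C24, a log2 difference of 3.61 (SE 0.074, adjusted p 6.8e-12). The floral integrator SOC1 (AT2G45660, AGL20 in the reference) had 40.3 ± 2.4 and 9.28 ± 1.07 RPKM, and the repressors SVP (AT2G22540) and MAF1 (AT1G77080) had 49.4 and 25.1 RPKM and 29.99 and 9.23 RPKM. The list did not pass (camera adjusted p 0.0736, or 0.425 with an estimated correlation). Its adjusted p was 0.0439 with the replicate number as a block and 0.036 without C24 clf replicate 2. Of 18 clock genes 4 were higher and 3 lower by both adjustments, with PRR3 (AT5G60100) at 2.39 and 11.6 RPKM and TCP11 (AT5G08330), also named CHE, at 66.2 and 38.1 RPKM. Camera pointed down while the clock median was 0.09 (adjusted p 0.582), and quantile normalization gave 1 higher and 3 lower members and a median of -0.029.

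Of 29 glucosinolate genes 16 were higher and 2 lower in C24 clf, or 16 and 3 adjusted over the list alone (median 0.51, adjusted p 0.0263, adjusted p = 0.562 with an estimated correlation). IMS2 (AT5G23020), a chain-elongation enzyme also named MAM3, was higher, at 22.7 against 1.74 RPKM. The call of the list ended without Col clf replicate 3 (adjusted p 0.117) or C24 clf replicate 1 (0.0571), and the replicate block gave 18 higher and 6 lower members and quantile normalization 15 and 4. Of 17 salicylic acid defence genes 11 were higher and 1 lower by both adjustments, among them WAK1 (AT1G21250) at 8.74 and 21.4 RPKM and DMR6 (AT5G24530), an enzyme that degrades salicylic acid, at 7.61 and 22.4 RPKM. ACD6 (AT4G14400) was the lower one, at 5.14 and 1.11 RPKM. With quantile normalization 7 salicylic acid members were higher and 2 lower. The list had a camera adjusted p of 0.0598 with it, and without it 0.0736, or 0.433 with an estimated correlation. It passed with the replicate block (0.0439), without Col clf replicate 2 (0.0192), without C24 clf replicate 3 (0.0256) and without the 3 libraries richest in rRNA (0.0206).

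Of 18 immune receptor and RPW8 genes 6 were higher and 8 lower in C24, or 7 and 9 adjusted over the list alone. AT1G58602, known as RPP7, had 24.5 and 2.77 RPKM, and RPM1 (AT3G07040) had 4.36 ± 0.15 RPKM in Col and was listed at 0 in all C24 libraries. ZAR1 (AT3G50950) was among the higher ones, at 35.4 and 60.7 RPKM. Of 21 auxin genes 5 were higher and 10 lower, or 5 and 11 adjusted over the list alone, and the synthesis enzyme TAA1 (AT1G70560) was lower at 7.57 and 1.91 RPKM. The receptor list had an adjusted p of 0.0174 (adjusted p = 0.433 with an estimated correlation) and the auxin list 0.0081 (adjusted p = 0.425 with an estimated correlation). Both calls ended with quantile normalization, at 0.0598 each, and with a filter of 5 RPKM, at 0.0782 and 0.0787.

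Flavonoid genes were lower in C24 clf, with 1 of 11 higher and 7 lower, or 1 and 8 adjusted over the list alone. The reductase gene DFR (AT5G42800) had 18.9 and 2.58 RPKM and the chalcone synthase gene TT4 (AT5G13930) 27.04 and 10.7 RPKM (list adjusted p 1.6e-04, adjusted p = 0.425 with an estimated correlation). Of 19 heat, cold and drought genes 6 were higher and 7 lower, or 6 and 8 adjusted over the list alone, with COR15A (AT2G42540) at 168 and 45.2 RPKM, KIN2 (AT5G15970) at 332 and 101 RPKM and LTI65 (AT5G52300) at 0.847 and 7.93 RPKM. This list had an adjusted p of 0.0263 (adjusted p = 0.425 with an estimated correlation). Its call ended with quantile normalization (0.187), with a filter of 5 RPKM (0.0733), without the 3 libraries richest in rRNA (0.222), and without Col clf replicate 1 (0.114), Col clf replicate 2 (0.16) or C24 clf replicate 2 (0.0903).

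Photosynthesis genes gave 1 higher and 16 lower calls among 27 in C24 clf by both adjustments (median -0.23, adjusted p 8.7e-05, adjusted p = 0.425 with an estimated correlation), but with quantile normalization 3 were higher and 1 lower and the list turned up, with an adjusted p of 0.395. The replicate block gave 4 higher and 17 lower. LHCA3 (AT1G61520), an antenna protein, had 5000 ± 195 and 2640 ± 136 RPKM and kept its call. The nuclear-listed rRNA gene AT3G41979 moved with these groups. Its level was 6359, 17796 and 2148 RPKM in the Col libraries and 365, 206 and 122 RPKM in the C24 libraries. The root marker list had 1 tested member, PYK10 (AT3G09260), which was higher in C24 at 102 and 213 RPKM. In all, camera called 7 of 13 lists at an adjusted p below 0.05, and with an estimated correlation 0 at an adjusted and 1 at an unadjusted p below 0.05.

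The clf F1 was then compared with the arithmetic mean of both parents, which an additive hybrid would match. Of the genes named by size of change, LURP1 (AT2G14560) lay farthest below it and had 3.14 RPKM in Col, 28.1 RPKM in C24 and 2.06 RPKM in the F1, a log2 difference from the mid-parent of -2.46. DMR6 had 3.91 ± 0.88 RPKM in the F1 (-1.72, adjusted p 5.2e-05), WAK1 5.29 ± 0.13 RPKM (-1.35, adjusted p 9.8e-05), PCC1 11.8 RPKM (-2.09) and the transcription factor WRKY70 (AT3G56400) 4.16 RPKM against 10.9 and 13.3 RPKM in Col and C24. SOC1 in the F1 stood at 7.80 ± 0.76 RPKM, near the C24 level (-1.55, adjusted p 1.7e-05). HPL1 (14.1 RPKM, -1.18), ICL (3.90 RPKM, -1.18), the stress-induced LTI78 (AT5G52310; 5.83 RPKM against 22.3 in Col and 4.0 in C24) and HIR2 (AT3G01290; 10.7 RPKM against 18.7 and 25.3) completed the 10 lowest.

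Genes above the mid-parent were fewer. ESM1 reached 215 ± 3.80 RPKM in the F1, near the Col level (0.77, adjusted p 0.0022), and DR4 (AT1G73330) 17.3 ± 2.02 RPKM against 14.6 in Col and 4.2 in C24 (0.82, adjusted p 0.0040). The myrosinase TGG2 (AT5G25980), which hydrolyses glucosinolates, had 503 RPKM in Col, 566 RPKM in C24 and 775 ± 32.9 RPKM in the F1 (0.54, adjusted p 0.0035). The arabinogalactan protein genes AGP21 (AT1G55330) and AGP17 (AT2G23130) had 212 and 45.7 RPKM in the F1, the copper transporter COPT2 (AT3G46900) 14.8 RPKM and the expansin EXPA8 (AT2G40610) 42.9 RPKM. MSRB6 (AT4G04840), CIB1 (AT4G34530) and RALFL33 (AT4G15800) had log2 differences of 0.63, 0.48 and 0.46. Of these 20 genes, 14 kept their calls with quantile normalization, which ended those of EXPA8 (0.60), HIR2 (-0.86), ICL (-1.01), LTI78 (-0.93), PCC1 (-1.95) and WRKY70 (-1.20), with the log2 difference under it in brackets. Without the filter 10 were called, without clf F1 replicates 1, 2 or 3 in turn 19, 10 and 9, without 1 parent library 16 to 18, and without the 3 libraries richest in rRNA 3. DR4, ESM1, TGG2, AGP21, LURP1, DMR6, SOC1, WAK1 and HPL1 kept theirs with quantile normalization and without any 1 library.

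limma called 1199 genes (6.73%) at an adjusted p below 0.05 against the mid-parent, 66 higher and 1133 lower, while 5691 had an unadjusted p below 0.05. The median log2 difference of all tested genes was -0.12, and with quantile normalization it was -0.02 with 101 higher and 285 lower calls, of which 294 were among the 1199. The count depended on single libraries: it was 179 without clf F1 replicate 3, 213 without clf F1 replicate 2, 386 without C24 clf replicate 3, 548 without C24 clf replicate 2, 603 without Col clf replicate 1, 613 without Col clf replicate 3 and 3377 without clf F1 replicate 1. Without the 3 libraries richest in rRNA, which left 1 F1 library, it was 3, namely LURP1, DMR6 and SOC1. It was 553 without the filter on low values and 4472 with the replicate block.

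By group, 9 of 17 salicylic acid defence genes fell below the mid-parent and 0 rose above it, or 13 and 0 adjusted over the list alone, with a median of -0.52 against -0.12 for all genes. NPR1 (AT1G64280), a salicylic acid receptor, had 12.2 RPKM in Col, 11.1 in C24 and 8.76 in the F1 (-0.37, adjusted p 0.0095), a call that ended without clf F1 replicate 3. The list's camera adjusted p was 1.9e-05 and its adjusted p = 0.243 with an estimated correlation; quantile normalization left 5 lower calls, and the replicate block gave 13. Of 18 immune receptor and RPW8 genes 10 were lower and 0 higher, or 14 and 0 adjusted over the list alone, including ZAR1 with 30.4 RPKM (-0.65, adjusted p 7.9e-04) and HR3 (AT3G50470) with 1.66 RPKM (-1.07). The receptor list did not pass (adjusted p 0.235), and 3 lower calls were left with quantile normalization. Of 19 heat, cold and drought genes 7 were lower and 0 higher, or 11 and 0 adjusted over the list alone (median -0.48). KIN2 had 130 RPKM in the F1 (-0.72, adjusted p 0.0059) and COR47 (AT1G20440) 207 RPKM against 257 and 258 in Col and C24 (-0.31), a call that quantile normalization ended. The replicate block gave 13 lower and quantile normalization 4. This list had a camera adjusted p of 0.0616, and of 0.569 with an estimated correlation. It passed with quantile normalization (0.0018), with the replicate block (0.0476), without the filter (0.0253), and without C24 clf replicate 2 (0.0147), C24 clf replicate 3 (0.0332) or clf F1 replicate 3 (0.0429).

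Of the flowering genes in the F1, FLC stood at 100 ± 6.18 RPKM, above the mid-parent (0.41, adjusted p 0.011), while SOC1, FT (AT1G65480; 4.57 ± 1.17 RPKM in Col, 2.29 in C24 and 1.4 ± 0.88 in the F1) and SVP (29.0 RPKM, -0.35) were below it. These were 1 higher and 3 lower of 22 genes, or 1 and 7 adjusted over the list alone and 1 and 8 with the replicate block (adjusted p 0.934 for the list). The FT call ended without the filter and without clf F1 replicate 2 or 3, and the SVP call with quantile normalization and without clf F1 replicate 3. Glucosinolate genes gave 4 higher calls, ESP, ESM1, TGG1 (AT5G26000) and TGG2, and 3 lower ones among 29, or 4 and 7 adjusted over the list alone and 4 and 19 with the replicate block. Quantile normalization left 2 higher and 0 lower calls. The ESP and TGG1 calls ended with quantile normalization (0.10 and 0.15), and that of ESP also without the filter, without Col clf replicate 1, any 1 C24 library, or clf F1 replicate 2 or 3. Their camera direction, on the mean of the parents' logs and against all other genes, was up (adjusted p 0.0026, adjusted p = 0.569 with an estimated correlation). Their median from the arithmetic mid-parent was -0.27. The call ended with the replicate block (0.161), quantile normalization (0.418), without Col clf replicate 3 (0.0817) and without clf F1 replicate 1 (0.152).

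Photosynthesis genes gave 2 higher and 0 lower calls of 27, or 9 and 0 adjusted over the list alone (median 0.13, adjusted p 2.4e-17, adjusted p = 0.243 with an estimated correlation), but with quantile normalization the median was -0.11, none was called and the adjusted p was 0.191. The replicate block gave 13 higher and 1 lower. LHCB2.2 (AT2G05070) had 3776, 2986 and 4355 RPKM in Col, C24 and the F1 and lost its call with quantile normalization, without the filter and without clf F1 replicate 2 or 3, and LHCB4.1 (AT5G01530) had 3658, 2983 and 3883 RPKM and went from 0.23 to -0.034 with quantile normalization. The LHCB4.1 call also ended without the filter and without any 1 of the Col libraries, C24 clf replicate 1 or 3, or clf F1 replicate 2 or 3. The rRNA gene AT3G41979 was at 1363, 14696 and 16022 RPKM in the F1 libraries. Seed, auxin and flavonoid lists were called upwards by camera (adjusted p 0.0279, 0.0225 and 0.0225, and adjusted p = 0.364, 0.364 and 0.569 with an estimated correlation) while their medians were -0.60, -0.06 and -0.002. Camera sets a list against all other genes, on differences from the mean of the parents' logs, while the medians are from the arithmetic mid-parent. An additive F1 lies above the mean of logs where its parents differ. The upward calls therefore do not show a raised F1 in these lists. Their members gave 0 higher and 0, 1 and 1 lower calls by both adjustments, the lower ones being WES1 (AT4G27260) and TT7 (AT5G07990), whose calls ended without C24 clf replicate 3 and without clf F1 replicate 2 or 3 (that of WES1 also with quantile normalization), and 1, 3 and 1 lower at an unadjusted p below 0.05. With the replicate block these were 1, 2 and 1 lower, and with quantile normalization 0, 0 and 1 lower and 1 higher auxin gene. These 3 list calls ended with quantile normalization (0.548, 0.191 and 0.418) and without clf F1 replicate 1 (0.278, 0.0771 and 0.312). Without the filter the adjusted p was 0.0849, 0.088 and 0.0596, and the seed call also ended without Col clf replicate 3 (0.0726) or clf F1 replicate 3 (0.0987), the auxin call without clf F1 replicate 2 (0.0818) and the flavonoid call without C24 clf replicate 2 (0.0563).

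The other lists did not pass against the mid-parent. EMF1 (-0.36, adjusted p 0.017) was the lower call of 21 Polycomb genes, with 2 adjusted over the list alone, and PI (-0.68, adjusted p 0.018) that of 12 floral genes, with 5 adjusted over the list alone (list adjusted p 0.767 and 0.387). The EMF1 call ended without clf F1 replicate 2 or 3, and that of PI without clf F1 replicate 2, without the filter and with quantile normalization. limma called 0 of 9 meristem genes (adjusted p 0.809), 0 of 18 clock genes (0.353) and the root marker PYK10 not, against 4, 5 and 1 lower at an unadjusted p below 0.05. Adjusted over the list alone the calls were 0, 0 and 1. The replicate block changed this, with 2 lower Polycomb genes (SWN and EMF1), 5 lower floral genes (SEP3 among them), 2 lower meristem genes (KNAT3 and KNAT4), 1 higher and 7 lower clock genes, and PYK10 lower. With quantile normalization 2 Polycomb genes were lower and 0 floral genes were called. The floral, flowering and clock medians (-0.24, -0.18 and -0.12) had the opposite sign to camera's direction, which is against all other genes and on the mean of logs. In all, camera called 6 of 13 lists on the mean of the parents' logs. With an estimated correlation it called 0, where 2 had an unadjusted p below 0.05.

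Against each parent, the F1 was closer to Col clf than to C24 clf. F1 and Col differed in 2140 genes, 888 higher and 1252 lower in the F1, and F1 and C24 in 7558 genes, 1186 higher and 6372 lower. With quantile normalization these were 1169 and 1171, and 2318 and 2401, and 1902 of the 2140 and 3475 of the 7558 genes were called again. The first count was 1337 without Col clf replicate 3, 1354 without Col clf replicate 1, 3551 with the replicate block and 556 without the 3 libraries richest in rRNA. The second was 4861 without C24 clf replicate 3, 5008 without clf F1 replicate 3 and 1566 without those 3 libraries. Spearman correlations across genes were 0.977 to 0.983 between F1 and Col libraries and 0.963 to 0.973 between F1 and C24 libraries, against 0.991 to 0.993 within groups. The rRNA gene AT3G41979 had 1363 to 16022 RPKM in F1, 2148 to 17796 in Col and 122 to 365 in C24 libraries. The closeness to Col could therefore not be separated from the make-up of the libraries. Of the 7935 genes that differed between the parents, 7061 (89.0%) did not pass the test against the mid-parent, which does not show that they were additive. Of the other 874, the F1 lay towards the lower parent in 831. In 716 of these C24 was the higher parent. Independent lists would share 361, but both tests use the same parent libraries. Simulated groups without a difference shared 0 in 20 draws, but their parents had equal levels, unlike the data. Neither value therefore weighs the 716. The 7061, 831 and 716 come from the fit without the replicate block. With the block, 9544 genes differed between the parents and 4472 from the mid-parent, and these classes were not counted again. Genes whose parents were at least 4-fold apart had a median F1 position, with Col at 0 and C24 at 1, of 0.32 where C24 was higher (161 genes, quartiles 0.228 and 0.437) and 0.52 where Col was higher (162 genes, 0.468 and 0.584).

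In 186 genes the F1 lay outside both parents, above them in 22 and below them in 164. DMR6 and WAK1 were below both, with F1 differences from Col of -0.82 (adjusted p 0.0017) and -0.62 (adjusted p 0.0045), and TGG2 was above both, by 0.62 from Col and 0.46 from C24. Independent lists of these lengths would share 59.1 genes above and 448 below. Both comparisons use the same F1 libraries and the parents differ in many genes, so these values do not weigh the 22 and 164. The count was 59 without clf F1 replicate 3, 77 without clf F1 replicate 2, 83 without Col clf replicate 1, 84 without Col clf replicate 3, 120 without C24 clf replicate 3 and 417 without clf F1 replicate 1. It was 574 with the replicate block and 10 without the 3 libraries richest in rRNA, and quantile normalization gave 49 above and 82 below.

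H3K27me3 was counted over the gene lists. In all 3 clf lists, peaks covered at least 200 bp of 24 of 26 floral MADS-box genes, 18 of 20 seed genes and 13 of 17 meristem genes, and of 0 of 28 photosynthesis genes and 0 of 19 clock genes. Against all genes of chromosomes 1 to 5, Fisher's exact test (two-sided, adjusted over 14 lists) gave 7.1e-17 for the floral, 1.7e-12 for the seed, 1.0e-07 for the meristem and 0.025 for the photosynthesis list. Glucosinolate genes (22 of 30, adjusted p 7.3e-12), salicylic acid defence genes (13 of 25, 5.4e-05), auxin genes (13 of 26, 7.7e-05), flavonoid genes (10 of 17, 8.9e-05) and root markers (7 of 13, 0.0024) also exceeded the genome's share. Flowering (8 of 26, 0.067), Polycomb (6 of 25, 0.300), receptor (2 of 21, 0.818), clock (0.128) and heat, cold and drought genes (3 of 21, adjusted p 1) did not pass; genes are not independent replicates here. Both wild-type libraries of Col, C24 and F1 marked 20, 17 and 20 floral genes, 8, 12 and 13 seed genes and 3, 8 and 5 meristem genes, and wild-type C24 replicate 2 marked 5 photosynthesis and 6 clock genes.

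SEP3, the seed regulator FUS3 (AT3G26790) and AGL17 (AT2G22630) had peaks in all 9 lists. On the TAIR10 build, the SEP3 peak of clf Col ran from 8592194 to 8597809 on chromosome 1 and covered 2588 bp of the gene. MAF5 (AT5G65080) had a peak in 8 lists, STM, FT, LEC2 (AT1G28300), MAF4 (AT5G65070) and DOG1 in 7 each, and WUS (AT2G17950) in 6. AG (AT4G18960) was marked in 5, namely all 3 clf lists and the second wild-type lists of Col and C24, and its clf Col peak ran from 10382923 to 10388476 on chromosome 4. FLC was marked in 4. Among the clf lists its peak was present in Col, from 3177114 to 3179772 on chromosome 5, and in neither C24 nor the F1, while wild-type C24 replicate 1 had a peak from 3176957 to 3181509. CLF itself had no peak in any list.

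**Figure D2:**
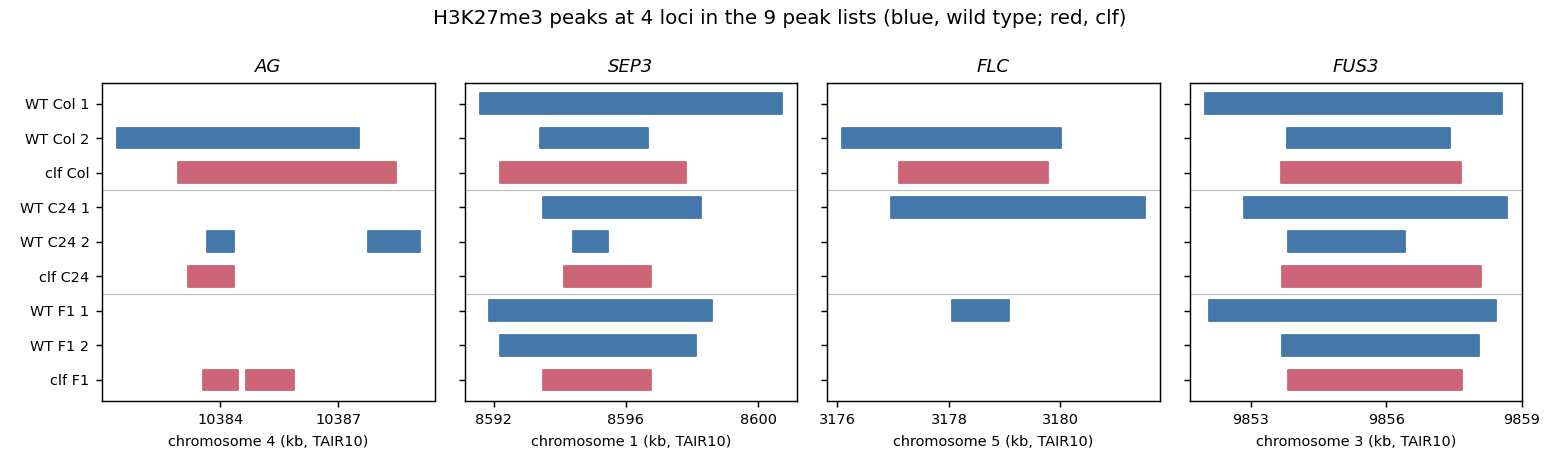
H3K27me3 peaks along 4 loci (horizontal axes, kb on TAIR10) in the 9 peak lists (vertical axis), each bar 1 peak from its start to its end, blue for wild type and red for clf. SEP3 and FUS3 carry a peak in all 9 lists, AG in 5 and FLC in 4.

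The comparison of wild-type Col and C24 asked where the mark differs between the accessions. Both libraries of Col and neither of C24 had a peak over 96 genes, both of C24 and neither of Col over 421, and all 4 over 1453. With equal numbers of peaks, Col-only and C24-only genes numbered 174 and 148. Peaks lie on TAIR10, the Col sequence, so C24 sequence differences could not be separated from a missing C24 peak. Among genes with a symbol, COW1 (AT4G34580), RLP38 (AT3G23120), NHX4 (AT3G06370), ACT9 (AT2G42090) and VPS24.2 (AT3G45000) had the greatest covered length of those marked in Col alone, and MAF1, TPS04 (AT1G61120), RE2 (AT4G02960), LUP5 (AT1G66960) and RHS6 (AT1G51880) of those marked in C24 alone. Peaks covered 4752 bp and 1558 bp of MAF1 in the C24 libraries. With 2 libraries against 2 no exact test can go below p = 1/3, so no gene was tested. The counts rested on single lists: replicate 1 lists marked 6194, 6266 and 6398 genes in Col, C24 and F1, and replicate 2 lists 2537, 5418 and 3984. Col-only genes numbered 192 without Col replicate 1, 1287 without Col replicate 2, 430 without C24 replicate 1 and 127 without C24 replicate 2. C24-only genes numbered 1478, 694, 2295 and 1172 without these libraries in turn.

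In the wild-type F1, a mark present in both parents was kept. Of the 1453 genes marked in all 4 parent libraries, 96.1% (exact binomial 95% interval 94.9 to 97.0) had a peak in both F1 libraries. Of the Col-only genes 30.2% (21.3 to 40.4) and of the C24-only genes 30.4% (26.0 to 35.0) did, against 0.0715% of the genes marked in no parent library. A peak in neither F1 library was found for 4.17% (1.15 to 10.3) of the Col-only and 20.2% (16.5 to 24.3) of the C24-only genes. The remaining genes had a peak in a single F1 library. MAF1 and COW1 were among the genes marked in both F1 libraries, and RLP38 and NHX4 were marked in the first alone. Col-only and C24-only shares with a peak in both F1 libraries did not differ (two-sided Fisher's exact p = 1), but leaving out a library moved both. Col-only shares were 18.8% and 3.34% without Col replicate 1 or 2, 61.2% without C24 replicate 1 and 93.8% without F1 replicate 2. C24-only shares were 55.0% without Col replicate 1, 6.36% and 16.5% without C24 replicate 1 or 2, and 48.5% and 61.8% without F1 replicate 1 or 2. Fisher's exact p with a library left out ran from 1.4e-141 to 0.0045, in either direction.

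Most of the mark was still called in the clf mutants. Of the genes marked in both wild-type libraries, 98.1% (1877 of 1914, interval 97.3 to 98.6) in Col, 92.5% (2965 of 3204, 91.6 to 93.4) in C24 and 94.0% (3110 of 3307, 93.2 to 94.8) in the F1 had a peak in the clf list of the same genotype. Genes with a peak in clf and in neither wild-type library numbered 932 in Col, 553 in C24 and 710 in the F1. These counts depended on the lists, and with equal numbers of peaks they were 393, 455 and 411. Without wild-type replicate 1 or 2 of the genotype they were 3446 and 1458 in Col, 2488 and 963 in C24, and 2622 and 1157 in the F1. In all genotypes 130 genes were marked in the 3 clf lists and in no wild-type list, and the widest with a symbol were TPS03 (AT4G16740), BGLU34 (AT1G47600), CYP709B1 (AT2G46960), CYP71B5 (AT3G53280) and CYP89A2 (AT1G64900). A peak in all 6 wild-type lists and no clf list was found over 1 gene, which has no symbol. That count is held down by the short wild-type list of Col replicate 2 (2537 genes). Of 2081 genes marked in the 5 other wild-type lists, 38 had a peak in no clf list. With the wild-type call from 1 library, the kept shares were 94.7% without Col replicate 1 and 70.9% without Col replicate 2, 62.3% and 78.2% for C24, and 89.3% and 78.5% for the F1. There is 1 clf list per genotype, so these differences have no replicate check, and peak presence does not measure the amount of the mark. Of the 889 genes marked in clf Col and not clf C24, 63.6% (60.3 to 66.7) had a peak in the clf F1, as did 56.9% (53.6 to 60.2) of the 903 marked in clf C24 and not clf Col, and 98.7% of the 4960 marked in both.

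Marked genes had little mRNA. The 4896 genes with a peak in all 3 clf lists had median levels of 0.05, 0.08 and 0.067 RPKM in Col, C24 and F1 clf, and 26.0%, 28.7% and 26.7% of them reached 1 RPKM. The 21572 genes without a peak in any list had medians of 3.53, 4.04 and 3.36 RPKM.

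Genes marked in 1 clf parent alone were then compared in mRNA, and those named are the largest changes with and against the mark. FLC, marked in clf Col and not in clf C24, was higher in C24, as were SADHU10-1 (AT3G58865; 2.04 and 16.4 RPKM), SGS3 (AT5G23570), a gene of small RNA production (8.95 and 35.1 RPKM), NAC047 (AT3G04070; 4.29 and 18.1 RPKM) and GSTU26 (AT1G17190; 6.28 and 24.4 RPKM). HR4, TRM9 (AT1G31600; 13.5 and 4.24 RPKM), RABA1g (AT3G15060; 13.2 and 5.5 RPKM), LP1 (AT2G38540; 756 and 402 RPKM) and PCN (AT4G07410; 21.5 and 11.98 RPKM) had the mark in clf Col alone and were higher in Col. C24 sequence differences could not be separated from a missing C24 peak or lower C24 mRNA at such genes. Of the 244 tested genes marked in clf Col alone 109 were higher in C24 and 48 in Col (median 0.23, camera adjusted p 0.272). Among genes marked in clf C24 alone, AGL87 (AT1G22590; 21.8 and 2.28 RPKM), COR15A, OPT7 (AT4G10770; 17.2 and 4.2 RPKM), Sadhu4-2 (AT1G03420; 20.5 and 6.09 RPKM) and AGP4 (AT5G10430; 18.5 and 5.45 RPKM) were higher in Col. SADHU3-1, GLYI4 (AT1G15380; 1.13 and 10.3 RPKM), WRR4 (AT1G56510; 6.67 and 18 RPKM), WAK1 and the nitrile specifier NSP1 (AT3G16400; 70.5 and 153 RPKM) were higher in C24. Of 308 such genes 91 were higher in C24 and 94 in Col. Their median was 0.02 against 0.13 for all genes, and camera pointed down (adjusted p 0.0014, adjusted p = 0.361 with an estimated correlation).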

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

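Peaks on the mitochondrial genome, which carries no histones and enters no comparison of the report, were found in all 9 lists, each above the 3 that a count of 0 allows. There were 14 in wild-type Col replicate 1, 14 in C24 replicate 1, 9 in F1 replicate 1, 19 in Col replicate 2, 24 in C24 replicate 2 and 15 in F1 replicate 2. The clf lists held 18 in Col, 24 in C24 and 19 in the F1. Their median fold enrichment exceeded that of nuclear peaks in 8 lists, with 12.7 against 5.05 in clf Col as the highest, and lay below it in wild-type F1 replicate 1, at 3.31 against 4.09. No explanation was tested.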

How the results depend on the processing

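Settings were chosen before the data were examined, except the fits without organelle and rRNA genes or without the 3 libraries richest in rRNA and the wild-type calls from replicate 1 or 2 lists alone. Of the results that answer a comparison, 158 values over the settings kept their side of the threshold or stayed within 1.5 times, 87 moved and 1 was weaker; of list results 383 kept theirs, 42 were weaker, 15 stronger and 2 reversed; of named genes 2172, 147, 30 and 1. The fits with a filter of 5 RPKM, other pseudocounts, nuclear genes alone, no organelle or rRNA genes and the mean of logs kept each count of calls they were run for within 1.5 times. limma-trend on log2 CPM was not run, as the values are RPKM. Depth limits calls of genes near 1 RPKM, which rest on few reads. A 2-fold minimum lowers counts by construction; otherwise the cause was not tested.

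Quantile normalization gave 386 genes for the F1 against the mid-parent, 4719 against C24, and 3 and 2 lists for C24 against Col and the mid-parent; photosynthesis turned in both (adjusted p 0.395 and 0.191), and LHCB4.1 to -0.034. No filter gave 553 genes against the mid-parent. The replicate block gave 4472 against the mid-parent, 3551 against Col and 574 outside both parents, and changed the calls of 4 lists (flowering and salicylic acid for C24 against Col, glucosinolate and heat, cold and drought against the mid-parent) and of members of lists, as the report gives them. It changed no call of the 20 genes named by size of change in either comparison. Without the 3 libraries richest in rRNA, which leaves 1 F1 library assumed to vary like the others, these were 3, 556 and 10, with 1566 against C24. A 2-fold minimum gave 1263 genes for C24 against Col, 39 against the mid-parent, 227 and 544 against Col and C24, and 4 outside both. With an estimated correlation 0 and 0 lists passed, and the set marked in clf C24 alone had an adjusted p of 0.361.

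For wild-type marking, Col-only and C24-only genes numbered 174 and 148 with equal numbers of peaks, 1420 and 1492 from replicate 1 lists, and 573 and 3454 from replicate 2 lists. The 50% of peaks with the highest scores gave 59 Col-only genes, and at least 50% of the gene body 265 C24-only genes. Col-only marks kept in the F1 were 44.4% and 58.1% from replicate 1 and 2 lists, and C24-only marks 57.0% from replicate 1 lists. Marks kept in clf Col, C24 and F1 were 88.4%, 86.7% and 83.8% with equal numbers of peaks, 96.7%, 87.3% and 90.3% with the highest scores, 70.9%, 78.2% and 78.5% from replicate 1 lists, and 94.7%, 62.3% and 89.3% from replicate 2 lists. For C24 and F1 they were 94.1% and 93.0% with 50% of the gene body and 94.4% and 96.3% for merged regions.

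With each library left out in turn, calls ran from 6299 to 8272 for C24 against Col, 179 to 3377 for the mid-parent, 1337 to 2292 against Col, 4861 to 8478 against C24 and 59 to 417 outside both. Lists called were 6 to 8 and 2 to 7, and adjusted p 0.0989 to 0.395 for the Col-only set and 3.0e-04 to 0.0092 for the C24-only set. Col-only genes ran from 127 to 1287 and C24-only genes from 694 to 2295, their shares in the F1 from 3.34% to 93.8% and 6.36% to 61.8%. Kept marks ran from 70.9% to 94.7% in Col, 62.3% to 78.2% in C24 and 78.5% to 89.3% in the F1.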

Other observations

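Genes listed at 0 in all libraries of 1 clf parent and with at least 5 RPKM in the other were more numerous on the Col side. There were 50 such genes listed at 0 in C24, as were ARGAH2 and SADHU1-1, and 13 listed at 0 in Col, as was SADHU3-1. The F1 level of the first set had a median of 48.7% of the Col level (quartiles 43.8% and 52.2%), and that of the second set 42.1% of the C24 level (28.7% and 48.5%). A peak in the clf list of the parent listed at 0 lay over 3 of the 50 and 4 of the 13. TAIR10 is the Col sequence, so a gene missing from C24 can be listed at 0, while a gene missing from Col is not listed. The larger number on the Col side cannot be separated from this.

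Tests chosen after the result was seen were those of the F1 following the lower parent, of gain of the mark in clf and of weaker replicate 2 samples, and the fits without the 3 libraries richest in rRNA. Other splits of the libraries into groups of the same sizes were fitted for each result. With 10 splits the share cannot go below 0.05. The real split called 7935 genes for C24 against Col, 2140 for the F1 against Col and 7558 for the F1 against C24, each time with 1 of 10 splits as high and a highest other count of 0. Lists called for C24 against Col gave 1 of 10 (real 7, highest other 6). The sets marked in clf Col alone and clf C24 alone gave 4 of 10 and 3 of 10 (real -log10 p 0.566 and 3.15, highest other 1.79 and 4.73). Over 100 splits of 9 libraries, the 186 genes outside both parents were reached by 1, the real one (highest other 0). The 6 lists called against the mid-parent were reached by 14 of 100 (highest other 8), so chance cannot be excluded. The 1199 genes against the mid-parent were reached by 2 of 100, and the other split called 2406. That split set Col clf replicates 1 and 2 and clf F1 replicate 2 against the 3 C24 libraries and the remaining 3, and it points to a structure of the samples. Among the 17 splits that, like the real one, hold each replicate number once per group, the highest other count was 2 against the mid-parent and 0 outside both parents, and 17 are too few for a share under 0.05. The other splits mix genotypes within a group, which widens the spread within groups, so the shares of 1 and 2 of 100 are not taken to exclude chance.

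Calls of the F1 against the mid-parent were mostly lower, 1133 of 1199. Quantile normalization left 73.8% of calls lower, between the bounds set for and against scaling as the cause, so scaling stays open. Without the 3 libraries richest in rRNA, which left 1 F1 library, too few genes were called to weigh these libraries. The 1120 lower calls in both fits had a median log2 difference of -0.32 (quartiles -0.45 and -0.22) instead of -0.39 (-0.51 and -0.32). Their median standard error rose from 0.086 to 0.119. These and the 63 higher calls in both fits kept their sign (100%), but they were chosen in a fit that holds these libraries. Over all 17612 genes tested in both fits, the median went from -0.13 to -0.06, and 78.2% kept their sign. An F1 that follows the lower parent was tested on 1165 genes whose parents lay at least 2-fold apart with quantile normalization, and it was nearer the lower parent in 65.9% of them (63.1% to 68.6%), in 77.4% of the C24-higher and 53.9% of the Col-higher genes, which lies between the bounds set and leaves it open. A biological cause in the hybrid stays open as well and was not tested on wild-type mRNA.

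Wild-type peak lists shared more genes between genotypes of the same replicate number than between replicates of a genotype. With equal numbers of peaks the replicate pairs still had a mean Jaccard index of 0.358, against 0.554 for the 6 pairs of the same number, which argues against fewer peaks as the whole cause. Of the genes in the C24 replicate 2 list 59.1% (57.8% to 60.5%) were in the replicate 1 list of C24, where 77.1% and 85.6% of the Col and F1 replicate 1 lists were. This argues against replicate 2 as only a weaker sample of the same marked genes in C24. In the F1, 83.0% (81.8% to 84.2%) also lay below 84.8% and 87.4%, by a smaller margin. In Col, 75.4% (73.7% to 77.1%) against 76.2% and 82.1% decides nothing. A weak list that also holds peaks at other genes would lower such a share too, so a weak C24 replicate 2 is not excluded. Its nuclear peaks held 840780 tags, the fewest of the 9 lists, and it marked 6 clock genes, where the other lists marked 0. A shared batch of libraries of the same number stays open: the highest replicate pair (F1, 0.444) exceeded the lowest pair of the same number (Col and C24 in replicate 2, 0.418), which met the bound set against it, but that bound ignored that Col and C24 also differ in genotype, and this reading was changed after the value was seen. No biological explanation was tested, since a replicate number is not a group of the design.

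In all 3 clf lists but not in wild-type Col replicate 1, 1148 genes carried a peak, AG, STM, WUS, FT, LEC2 and DOG1 among them. Their peaks in wild-type Col replicate 2 were wider over the 462 genes that have one, with a median of 1730 bp (1619 to 1810) against 1309 bp (1280 to 1337), but in clf Col the medians were 2089.5 bp (1987 to 2184) and 2028 bp (1980 to 2059.5), so wide domains missed by that library stay open, a reading changed after these values were seen. Their fold enrichment in clf Col was lower, at 4.32 (4.21 to 4.41) against 5.79, so weak marking below the threshold may contribute, though not in that library alone, since wild-type C24 replicate 1 marked 57.8% and F1 replicate 1 46.7% of these genes, against 96.8% and 98.6% of the others. Wild-type Col replicate 2 had a peak over 40.2% of them (37.4% to 43.2%), against 46.5% of the other genes marked in the clf lists, which argues against gain of the mark in clf as the whole cause. A gain at some of these genes stays open. Among the loci named, the clf Col folds of LEC2 (9.28), FT (8.69), DOG1 (6.29) and WUS (5.9) lay above 5.79. Those of STM (5.35) and AG (4.2) lay below it.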
